A study of Homo sapiens with 6 samples.

How the data were processed

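RNA was sequenced from primary myometrial cells of 3 donors, each donor's cells carrying either an empty lentiviral vector or a vector for V5-tagged HMGA2, which gave 6 libraries. Per the labels' protocols, cells were freed from tissue by enzymes, passaged 2 times and transduced for 18 h with polybrene at 6 µg/ml, and transduced cells were selected with puromycin at 2 µg/ml. The labels' protocols give stranded mRNA libraries from 100 ng of RNA, loaded at 2 nM and read as pairs of 42 cycles on a NextSeq. The values in the deposited files were whole counts of read pairs per gene, made by the authors with STAR on the GRCh38 build per the labels, with no normalization. The STAR version and the annotation release were not given in the sources used here. Each file held 58336 gene IDs, of which 57754 had a current symbol and 58216 were in GENCODE release 29, whose gene coordinates and types were used here.

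Of the 3 count columns in a file, the column for the strand of the library kit was used, since the opposite strand held 5.24 to 5.94% of the counts of both strands. Counts assigned to genes were 9899481 and 11273739 for donor 1 (empty vector and HMGA2), 13697716 and 14582514 for donor 2, and 15010133 and 15257640 for donor 3. The libraries held 11807465 to 18389193 read pairs. Pairs outside genes (unmapped, mapped to several places, in no gene or in several genes) made up 14.4 to 16.2% with the empty vector and 17.0 to 18.8% with HMGA2. Pairs that map to several places were listed apart from the gene counts. Genes with near-identical copies, such as the keratin genes KRT14 and KRT17 and the CYP4F genes, can therefore lose pairs, which was not measured per gene. No library was a copy of another: the smallest chi-square per degree of freedom between 2 libraries was 32.8.

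Genes were tested in edgeR 4.0.16 under R 4.3.3 with the robust quasi-likelihood test, after filterByExpr with its default settings (14355 genes kept) and TMM normalization, and p values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The model held the group alone (4 residual degrees of freedom). The donor was added as a block in an alternative fit (2 residual degrees of freedom). The donor numbers pair the libraries: after removal of the group means, the correlation of log2 CPM between the 2 libraries of a donor was 0.51, 0.21 and 0.49, against −0.43 to 0.04 between libraries of different donors. SE is the standard error of the fitted log2 fold change, and CPM values use TMM-scaled totals. Folds from a count of 0 use a floor of 3 counts over the group, the upper 95% limit of a count of 0, and such floors cover counting error only. Fits without 1 library pool the spread over both groups, and fits without a donor leave 2 libraries per group.

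The genes named in the text followed a rule fixed before the data were examined. HMGA2 came first. Among genes past the threshold in either fit, with a symbol, a mean log2 CPM of at least 1 and the same direction in all 3 donors, the 12 with the largest folds in each direction were taken, and the 5 with the smallest p in each direction, genes of the group fit first. Each gene list added up to 4 members past the test, or its most abundant member where none passed. Genes outside this rule are named as chosen after their values were seen.

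Gene lists (35, with 887 entries, 780 of them tested) were written from general knowledge before the data were examined and tested with camera in limma 3.58.1 with a preset correlation of 0.01. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes, were the alternatives. The count adjusted over the list alone applies Benjamini-Hochberg to the members of that list. By fry's test for change in either direction 23 lists passed.

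The code was tested on simulated data with 200 of 14355 genes changed. The data were simulated apart for each fit from that fit's own model, so only those for the donor-block fit held donor differences. The group fit recovered 8% of genes changed 2-fold and 68% of those changed 4-fold, with 84 calls of which 8 were false. The donor-block fit recovered 48% and 93%, with 161 calls of which 20 were false. Of 35 unchanged lists 0 were called in either fit. Simulated genes were drawn independently of each other, so this count says nothing about lists whose genes move together. In the real data the estimated correlation reached 0.79 for cell cycle genes. A simulated list with a true change was called by camera with the preset correlation in both fits. With an estimated correlation it was called in the group fit (adjusted p = 0.00075) and missed in the donor-block fit (adjusted p = 0.0659).

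Alternatives planned before the data were examined were the donor block, size factors of the DESeq2 kind, library totals, removal of HMGA2 before normalization, no filter, a filter of 1 CPM in 3 libraries, unstranded counts, DESeq2 1.42.0, limma-voom, a fit without robust estimation, a minimum fold of 1.5, and leaving out each donor and each library. A correction for GC content and transcript length (a smooth fit with mgcv 1.9.3) and some combinations with the donor block were added after the data were seen. Permutation tests were run in R, and files were read and figures drawn with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9. Genes on the Y chromosome and XIST were kept in the fits and are not named.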

Results

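Raising HMGA2, an architectural chromatin protein that binds AT-rich DNA and is switched on in a subset of uterine leiomyomas, was the single planned difference between the 2 groups of primary human myometrial cells compared here. HMGA2 transcripts stood at 27.0 ± 13.9 CPM (counts scaled to a common library total, mean ± SD of 3 donors) with the empty vector and at 1789 ± 287 CPM with the HMGA2 vector. This was a log2 fold change of 6.05 (SE 0.49), or 66.2-fold, with an adjusted p of 0.00256 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The counts of HMGA2 rose in each donor, from 263 to 25481, from 580 to 25523 and from 160 to 25049. With the donor as a block the log2 fold change was 6.18 (SE 0.37).

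Beyond HMGA2, the genes that fell included POSTN, COL3A1, HAS2, FGF7 and HGF, and those that rose included KRT17, ADAMTS8, ADAMTS15, CPA4 and BTG2. Of 14355 genes tested, 372 changed in the group comparison without a donor block, 260 higher and 112 lower (69.9% higher), by edgeR's quasi-likelihood test with a false discovery rate of 0.05. All 372 moved the same way in all 3 donors, 350 changed at least 2-fold and 211 at least 4-fold. Under the donor block 1129 genes changed, 673 higher and 456 lower, and these included all 372 genes with the same direction. Among the 372 genes, 340 were protein coding, 17 were long intergenic noncoding RNAs and 8 were antisense transcripts. The 3465 genes whose values did not overlap between the groups made up 24.1% of those tested, against 10% by chance for 6 exchangeable libraries, a figure that leaves out the pairing by donor. The split into higher and lower depended on a joint correction for GC content and transcript length: with it 261 genes were higher and 180 lower, which put 59.2% on the higher side. The same correction with the donor block gave 666 higher and 752 lower (47.0% higher), and library totals in place of TMM gave 369 higher and 93 lower (79.9% higher). Leaving out donor 2 left 0 genes past the threshold by edgeR, with 1444 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0537. The same 2 remaining donors gave 1156 genes with the donor block. Leaving out donor 1 left 68 genes and leaving out donor 3 left 120.

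**Figure D1:**
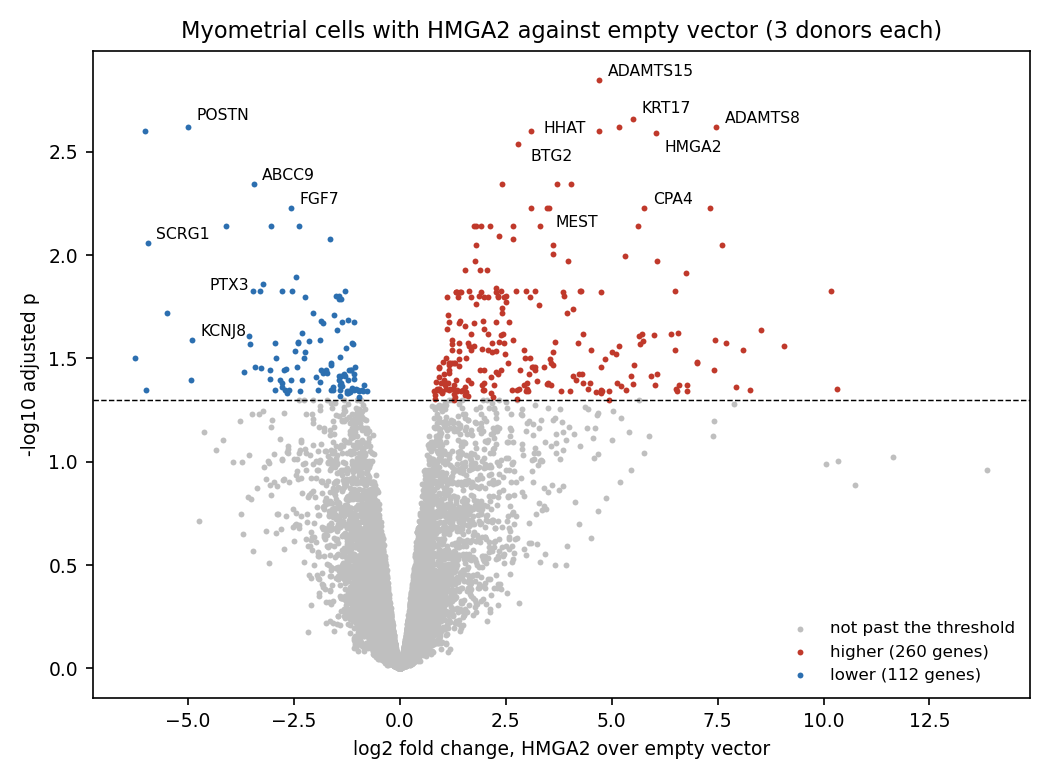
Log2 fold change (HMGA2 over empty vector, horizontal axis) against minus log10 of the adjusted p (vertical axis), 1 point per tested gene, in the group comparison of 3 against 3 libraries, with red for genes called higher, blue for genes called lower and the dashed line at an adjusted p of 0.05. ADAMTS15 and KRT17 had the smallest adjusted p on the higher side, and POSTN on the lower side.

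The largest rises fell in genes of many kinds. ADAMTS8 and ADAMTS15, neighbouring genes for secreted metalloproteases that act on the matrix, both rose. ADAMTS8 went from 0.150 ± 0.130 to 26.2 ± 1.85 CPM (log2 fold change 7.47, SE 0.56, edgeR adjusted p = 0.00239) and ADAMTS15 from 3.49 ± 0.907 to 91.9 ± 12.6 CPM (4.71, SE 0.27, adjusted p = 0.00142). CPA4, a secreted carboxypeptidase, rose from 27.3 ± 18.7 to 1483 ± 271 CPM (5.77, SE 0.57, edgeR adjusted p = 0.00592). KRT17, a keratin of epidermal appendages, rose from 1.67 ± 0.711 to 77.0 ± 14.3 CPM (5.51, SE 0.36, edgeR adjusted p = 0.0022). IVL, the involucrin precursor of the cornified envelope, rose from 3.77 ± 3.64 to 237 ± 190 CPM (6.02, SE 1.08, edgeR adjusted p = 0.0426). HSD3B1, an enzyme of steroid hormone synthesis, rose by 7.41 (SE 1.25, edgeR adjusted p = 0.0361). The glycosyltransferase gene B4GALNT2 rose by 7.32 (SE 0.70), the synaptotagmin gene SYT12 by 6.39 (SE 0.96) and CLCA2, a chloride channel regulator, by 5.16 (SE 0.38). Gains were also called for ACTBL2, an actin-like gene (5.01, SE 0.81), NDRG2, a stress-responsive gene (4.84, SE 0.83), and HHAT, which acylates hedgehog ligands (3.09, SE 0.24, edgeR adjusted p = 0.00251). TGM2, a crosslinking enzyme chosen after its values were seen, was the most abundant transcript of 1 HMGA2 library and rose by 2.31 (SE 0.32, edgeR adjusted p = 0.0160).

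The largest decreases were likewise mixed in kind. POSTN, the matricellular protein periostin, fell from 199 ± 26.1 to 6.20 ± 2.65 CPM (log2 fold change −5.01, SE 0.36, edgeR adjusted p = 0.00239), a 32.1-fold decrease. SCRG1, a secreted protein of mesenchymal stem cells, changed by −5.94 (SE 0.66, edgeR adjusted p = 0.00875). KCNJ8 and ABCC9, which encode the pore and the sulfonylurea receptor of an ATP-sensitive potassium channel of smooth muscle and pericytes, both fell. Their log2 fold changes were −4.90 (SE 0.75, edgeR adjusted p = 0.0257) and −3.44 (SE 0.32, adjusted p = 0.00454). The protocadherin gene PCDH10 changed by −4.10 (SE 0.43), the peptidase inhibitor gene PI16 by −3.56 (SE 0.56) and PRR16, a regulator of cell size, by −3.31 (SE 0.44). PTX3, a secreted pentraxin of innate immunity, changed by −3.22 (SE 0.40), and the noncoding gene MAP3K4-AS1 by −3.54 (SE 0.58), each called by edgeR with a false discovery rate of 0.05.

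**Figure D2:**
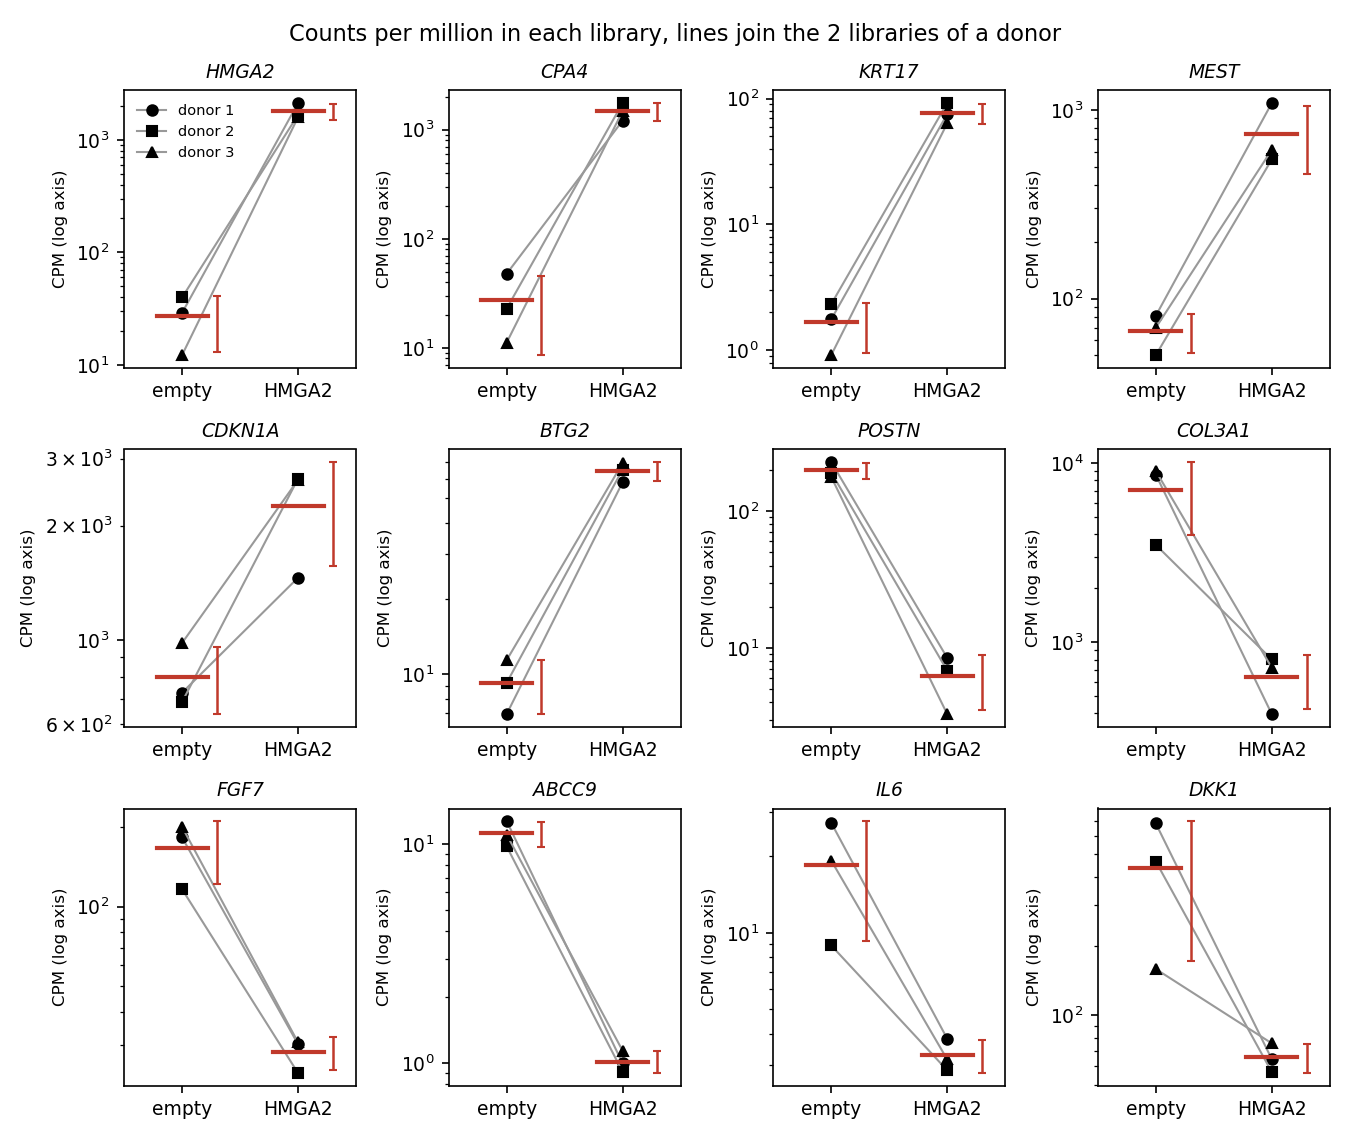
CPM on a log axis for 12 genes in the empty vector and HMGA2 libraries of the 3 donors (symbols, joined by a line for each donor), with a red bar at the mean of a group and a red error bar beside it for the SD. HMGA2, CPA4, KRT17, MEST, CDKN1A and BTG2 were higher and POSTN, COL3A1, FGF7, ABCC9, IL6 and DKK1 lower in all 3 donors.

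Contractile genes of smooth muscle gave no call without the donor block, and genes of excitability did. Among the latter, KCNJ8 and ABCC9 fell. The list of myometrial excitability genes and uterotonic receptors (23 tested) had 1 gene higher and 2 lower (2 and 7 when adjusted over the list alone) and a median log2 fold change of −0.52. Its camera adjusted p was 0.00879 with the preset correlation and its adjusted p = 0.640 with an estimated correlation. Under the donor block 2 of its genes were higher and 7 lower, among them PTGS2, the inducible prostaglandin synthase (−3.86, SE 0.34, edgeR adjusted p = 0.00173). The smooth muscle contractile list (30 tested) had 0 genes past the edgeR threshold (2 higher and 3 lower over the list alone, median −0.17, camera adjusted p = 0.297). Under the donor block it had 2 higher and 5 lower. The contractile actin gene ACTG2 changed by −3.10 (SE 0.49, edgeR adjusted p = 0.0127), the calcium pump inhibitor gene PLN by −3.08 (SE 0.59, adjusted p = 0.0239) and SYNPO2 by −1.54 (SE 0.19, adjusted p = 0.00574). MYOCD, the coactivator that drives smooth muscle genes, moved the other way, by 2.24 (SE 0.38, adjusted p = 0.0158) in the donor-block fit of edgeR.

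Several matrix transcripts fell. COL3A1, a fibrillar collagen of the uterine wall, fell from 7038 to 639 CPM (log2 fold change −3.46, SE 0.46, edgeR adjusted p = 0.0150). COL5A2 changed by −2.39 (SE 0.39), the collagen prolyl hydroxylase gene P4HA3 by −2.42 (SE 0.43) and the crosslinking oxidase gene LOXL3 by −2.31 (SE 0.43). COL12A1 (−2.62) and LOX (−1.41), named after their values were seen, also fell by edgeR with a false discovery rate of 0.05. Of 34 collagen and collagen-processing genes 0 were higher and 6 lower (1 and 10 over the list alone, 3 and 12 with the donor block), and the list median was −0.63. The camera adjusted p was 2.7e-06, against an adjusted p = 0.640 with an estimated correlation. HAS2, which makes hyaluronan, changed by −3.06 (SE 0.55) and the basement membrane gene NID1 by −1.16 (SE 0.21). Together with POSTN these were the 3 lower genes among 40 matrix glycoprotein and proteoglycan genes (1 higher and 7 lower over the list alone, 1 and 10 with the donor block). The median of that list was −0.33 and its camera adjusted p 0.00227, or adjusted p = 0.640 with an estimated correlation. In the donor-block fit the laminin gene LAMA2 changed by −1.39 (SE 0.17). Among 26 matrix proteases and inhibitors, the protease gene ADAMTS6 changed by −2.39 (SE 0.25, edgeR adjusted p = 0.00721) and was the single call (2 higher and 2 lower over the list alone, median −0.32, camera adjusted p = 0.193). The donor block gave that list 3 higher, ADAMTS9 (1.28, SE 0.24) among them, and 4 lower, with MMP16 at −1.98 (SE 0.38).

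Signalling genes moved in both directions. FGF7, a growth factor that stromal cells send to epithelia, fell from 166 ± 44.2 to 28.1 ± 4.02 CPM (−2.57, SE 0.25, edgeR adjusted p = 0.00592). HGF changed by −3.67 (SE 0.65) and the lymphangiogenic factor gene VEGFC by −2.78 (SE 0.37), while the receptor gene KIT rose by 4.10 (SE 0.76). These 4 genes were the calls among 30 growth factors and receptor tyrosine kinases (1 higher and 5 lower over the list alone, 2 and 6 with the donor block, median −0.08, camera adjusted p = 0.0529). For WNT signalling, WNT4 rose by 2.99 (SE 0.57, edgeR adjusted p = 0.0417), and WNT2 (−2.84, SE 0.54) and the WNT antagonist gene DKK1 (−2.73, SE 0.48, adjusted p = 0.0358) fell. That list of 26 genes (5 higher and 2 lower over the list alone and also with the donor block, where the WNT feedback gene NKD1 was at 4.62, SE 0.70) had a median of 0.057 and a camera adjusted p of 0.554. TGFB2, a ligand of the TGF-beta family, rose by 2.07 (SE 0.29), as did BAMBI, a decoy receptor (1.99, SE 0.39). FSTL3, an activin antagonist, changed by −1.74 (SE 0.32), which made 3 edgeR calls among 35 TGF-beta and BMP genes. Adjusted over that list alone 7 were higher and 5 lower, and with the donor block 6 and 5, with ID3 at −1.33 (SE 0.15). Its median was 0.065 and its camera adjusted p 0.554. In the IGF axis (20 tested), the insulin receptor substrate gene IRS1 rose by 1.16 (SE 0.17) and PAPPA2, which cleaves IGF-binding proteins, changed by −2.94 (SE 0.48). That list had 1 higher and 3 lower over the list alone and 2 and 3 with the donor block (H19 at 2.94, SE 0.38, and IGFBP6 at −1.31, SE 0.25). The IGF axis had a median of 0.19 and a mean of 0.10 although camera ranked it lower (adjusted p = 0.981).

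Genes known from leiomyoma tissue did not move as a set. MEST, an imprinted gene of mesoderm, rose from 67.1 ± 15.7 to 748 ± 294 CPM (3.48, SE 0.34, edgeR adjusted p = 0.00592). WNT4 also rose, whereas COL3A1, COL5A2 and POSTN fell, although all 5 belong to the 26 tested genes reported higher in leiomyoma. That list had 4 higher and 3 lower over the list alone, a median of −0.12 and a camera adjusted p of 0.375. The 23 genes reported lower in leiomyoma had 0 higher and 1 lower by edgeR (1 higher and 1 lower over the list alone, median −0.46, camera adjusted p = 0.255). In the donor-block fit 1 of these was higher, JUN (1.28, SE 0.25), and 5 were lower, with the retinal dehydrogenase gene ALDH1A1 at −4.05 (SE 0.52) and EGR1 at −1.62 (SE 0.23). The list then passed (camera adjusted p = 0.0372, adjusted p = 0.578 with an estimated correlation). Of 8 genes tied to the HMGA2 subtype of leiomyoma, PAPPA2 was lower (1 higher and 1 lower over the list alone, median 0.22, camera adjusted p = 0.981), and the cyclin gene CCND2 passed with the donor block alone (1.49, SE 0.27). Steroid hormone receptors and targets (17 tested) had 0 genes past the edgeR threshold in either fit (0 higher and 1 lower over the list alone, median −0.26, camera adjusted p = 0.193), with CITED2 at 0.19 (SE 0.25).

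Several targets of p53 rose. BTG2, which slows proliferation, rose from 9.20 ± 2.22 to 64.1 ± 5.63 CPM (2.79, SE 0.23, edgeR adjusted p = 0.00291). The stress cytokine gene GDF15 rose from 53.5 ± 5.47 to 343 ± 128 CPM (2.68, SE 0.29, edgeR adjusted p = 0.00721). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose from 798 to 2251 CPM (SE of log2 fold change 0.30, edgeR adjusted p = 0.0450). DDB2, a damage recognition gene, rose by 1.68 (SE 0.26) and RRM2B, a ribonucleotide reductase subunit, by 1.44 (SE 0.20). With FDXR (2.09) and XPC (0.92), named after their values were seen, these were the 7 higher genes of 22 tested, with 0 lower and 17 higher over the list alone. The list median was 0.81 and the camera adjusted p 3.3e-15, or adjusted p = 0.0471 with an estimated correlation. This was the single list that kept its call with an estimated correlation, and it also passed by fry (adjusted p = 0.00548). Under the donor block the camera adjusted p was 1.86e-13, but adjusted p = 0.463 with an estimated correlation. MDM2, the p53 target that limits p53 itself, was at −0.02, TP53I3 at −0.63 and SESN2 at −0.51, all 3 named after their values were seen.

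Cell cycle transcripts leaned lower in a way that rested on donor 2. None of the 35 cell cycle genes passed by edgeR in either fit or over the list alone (0 higher and 0 lower), with MCM7, a subunit of the replicative helicase, at −0.62 (SE 0.38). The list median was −0.67 and its camera adjusted p 0.00528, or adjusted p = 0.768 with an estimated correlation. Without donor 2 the mean of the list turned to 0.18 (camera adjusted p = 0.291). Among 20 cyclins, inhibitors of cyclin-dependent kinases and senescence genes, CDKN1A and GDF15 rose and the kinase inhibitor gene CDKN2C changed by −1.41 (SE 0.29, edgeR adjusted p = 0.0479). That list had 3 higher and 2 lower over the list alone, a median of −0.12 and a camera adjusted p of 0.981 on the higher side.

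Inflammatory and stress genes gave few calls. IL6, a cytokine of the senescence secretome, fell from 18.4 ± 9.14 to 3.28 ± 0.489 CPM (−2.48, SE 0.42, edgeR adjusted p = 0.0292) and was the single call among 14 cytokines and chemokines (0 higher and 1 lower over the list alone, median −0.61, camera adjusted p = 0.235). Under the donor block CXCL8 was a further lower gene (−2.55, SE 0.39, edgeR adjusted p = 0.0164). IFI35 changed by −2.23 (SE 0.38, edgeR adjusted p = 0.0293), the single call among 23 interferon response genes (0 higher and 1 lower over the list alone, median −0.26, camera adjusted p = 0.215). IFIT1 was at −1.65 (SE 0.24) with the donor block, which called 2. Immediate early and AP-1 genes (20 tested) had 0 edgeR calls (1 higher and 0 lower over the list alone, median −0.40, camera adjusted p = 0.112). The donor block called JUN higher and FOSB (−1.71, SE 0.40) and EGR1 lower, and the camera adjusted p was 0.0339, or adjusted p = 0.578 with an estimated correlation. Of 24 unfolded protein response genes 0 passed (0 over the list alone), yet the list fell with a median of −0.52 and a camera adjusted p of 0.000278, or adjusted p = 0.640 with an estimated correlation. Its 3 lower genes with the donor block were ATF4, the transcription factor of the integrated stress response (−0.84, SE 0.19), PPP1R15A (−1.09, SE 0.22) and the chaperone cofactor gene MANF (−1.11, SE 0.23).

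Genes of metabolism, chromatin and translation gave few calls. EGLN3, an oxygen-sensing hydroxylase, rose by 4.50 (SE 0.72, edgeR adjusted p = 0.0288) and was the single call among 30 glycolysis and hypoxia genes (1 higher and 0 lower over the list alone, median −0.05, mean 0.13, camera adjusted p = 0.981). The carbonic anhydrase gene CA12 joined it with the donor block (1.22, SE 0.16). Cholesterol synthesis (23 tested) had 0 edgeR calls over all genes or over the list alone (median 0.09, camera adjusted p = 0.568). There 2 genes were lower with the donor block, INSIG1 among them (−1.17, SE 0.26). Among 37 chromatin modifiers and HMG proteins 0 passed in the group fit, also over the list alone (median −0.17, camera adjusted p = 0.193). The nucleosome-binding gene HMGN2 was lower with the donor block (−0.90, SE 0.18). The 27 HOX genes had 0 calls in any of these edgeR tests (median 0.14, camera adjusted p = 0.235), with HOXA11, which patterns the uterus, at 0.06 (SE 0.20). Cytosolic ribosomal protein genes (40 tested, 0 calls over all genes or the list alone, RPL3 at −0.27, SE 0.29) had a median of −0.21 and a camera adjusted p of 0.00879, or adjusted p = 0.768 with an estimated correlation. Without donor 1 the camera adjusted p of the ribosomal list was 0.144. Nuclear-encoded oxidative phosphorylation genes (35 tested) had 0 calls over all genes or the list alone (median −0.01, camera adjusted p = 0.875). NDUFA4 at −0.66 (SE 0.15) was the single lower gene with the donor block. Mitochondrially encoded genes (13 tested) had 0 calls in all of these tests (median −0.16, camera adjusted p = 0.429), with MT-CO1 at −0.13 (SE 0.26).

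Markers of other cell types and of adhesion changed gene by gene. KRT7, a keratin of simple epithelia, rose by 1.95 (SE 0.39, edgeR adjusted p = 0.0450), the single call among 9 epithelial markers (3 higher and 0 lower over the list alone). The epithelial list had a median of 1.01 and a camera adjusted p of 0.00501, or adjusted p = 0.640 with an estimated correlation. The donor block added KRT18 (1.89, SE 0.22), KRT8 (2.20, SE 0.33) and KRT19 (0.87, SE 0.17), which made 4. KCNJ8 and ABCC9 were the 2 lower genes among 8 pericyte markers (0 higher and 3 lower over the list alone, median −0.16). Their camera adjusted p was 0.0234, or adjusted p = 0.640 with an estimated correlation. The pericyte call was lost with the donor block (camera adjusted p = 0.0587) and without donor 3 (adjusted p = 0.186). RGS5 was higher (2.16, SE 0.32) and NOTCH3 lower (−1.28, SE 0.20) with the donor block. FAP, a protease of activated fibroblasts, changed by −1.57 (SE 0.31, edgeR adjusted p = 0.0436) and with PI16 made the 2 lower genes of 14 fibroblast markers (0 higher and 2 lower over the list alone, 1 and 3 with the donor block, median −0.61, camera adjusted p = 0.142). FLT1, a VEGF receptor, rose by 2.48 (SE 0.42, edgeR adjusted p = 0.0301) as the single call among 8 endothelial markers (1 higher and 0 lower over the list alone, median −0.22, camera adjusted p = 0.981). TEK was lower with the donor block (−0.98, SE 0.23). PCDH10 was the single call among 27 adhesion and integrin genes (2 higher and 3 lower over the list alone, median −0.14, camera adjusted p = 0.193). In the donor-block fit ITGA3 (1.16, SE 0.20) was among 2 higher and the cadherin genes CDH2 (−1.95, SE 0.20) and CDH6 (−4.67, SE 0.36) among 4 lower.

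Many members of the remaining marker lists had too few counts to be tested. Tested were 3 of 20 leukocyte, 4 of 8 mesothelial and 6 of 12 neural and Schwann markers. Leukocyte markers (3 tested, 0 edgeR calls, 1 higher and 0 lower over the list alone) had a median of 2.94 and a camera adjusted p of 0.193. Under the donor block the antigen presentation genes CD74 (3.03, SE 0.30) and HLA-DRA (3.77, SE 0.74) rose. The leukocyte list, with its 3 tested members, then passed (camera adjusted p = 0.00302, adjusted p = 0.578 with an estimated correlation). Mesothelial markers (4 tested, 0 edgeR calls, 1 higher and 0 lower over the list alone, median 0.83, camera adjusted p = 0.193) passed with the donor block (adjusted p = 0.0459, adjusted p = 0.578 with an estimated correlation), where CALB2, the calcium buffer calretinin, rose by 4.11 (SE 0.52). Of 6 neural and Schwann markers 0 passed, also over the list alone (median −0.05, mean 0.22, camera adjusted p = 0.981 on the higher side). In the donor-block fit the neurotrophin receptor gene NGFR rose (3.90, SE 0.35) and STMN2 was at −2.88 (SE 0.26). In all, 9 of 35 lists passed by camera with the preset correlation (2 higher and 7 lower), 12 with the donor block (8 of them in both), 1 with an estimated correlation and 1 by fry.

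**Figure D3:**
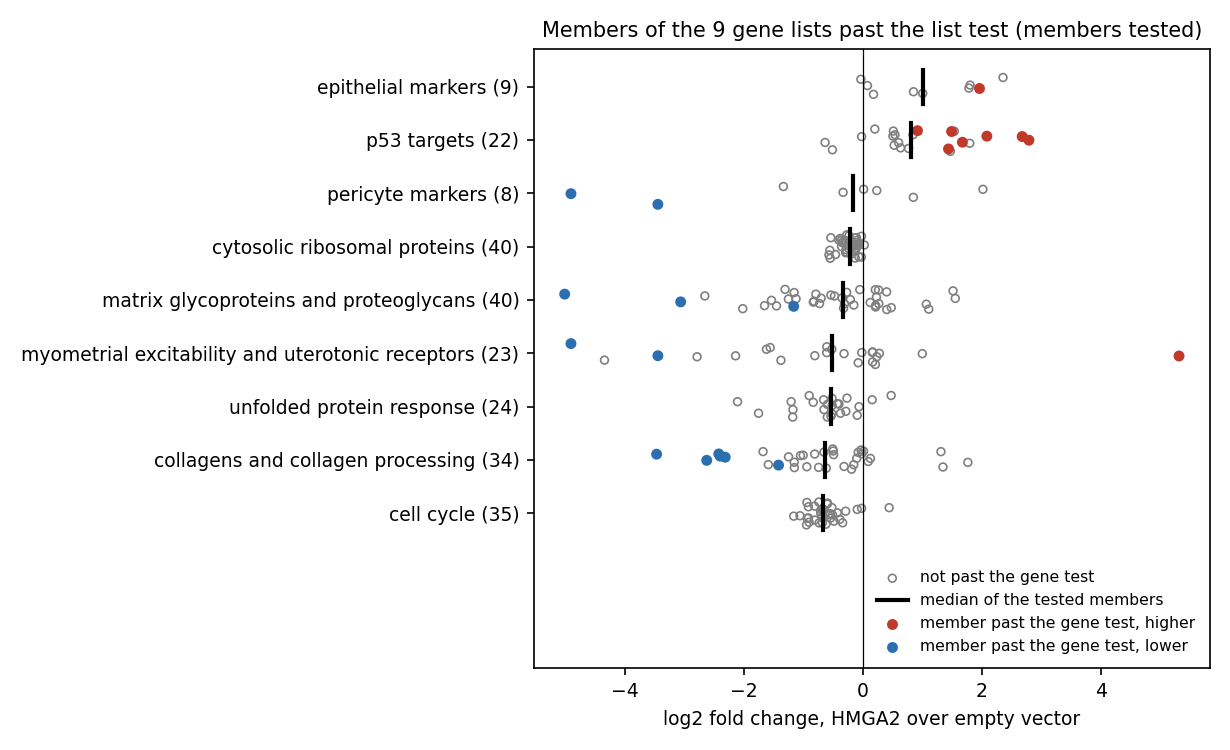
Log2 fold change (HMGA2 over empty vector, horizontal axis) of each tested member of the 9 gene lists that passed camera with the preset correlation, 1 point per gene, filled where the gene passed (red higher, blue lower), with a black bar at the list median. The p53 target list had a median of 0.81 and the cell cycle list a median of −0.67.

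Values per library had limits of their own. Read pairs in no annotated gene made up 2.70 ± 0.53% of pairs with the empty vector and 3.76 ± 0.73% with HMGA2, higher with HMGA2 in 3 of 3 donors (2-sided exact permutation p = 0.2). All pairs outside genes made up 14.4 to 16.2% with the empty vector and 17.0 to 18.8% with HMGA2, higher with HMGA2 in each donor (2-sided exact permutation p = 0.1). Genes with at least 1 count numbered 19972 ± 322 with the empty vector and 21551 ± 688 with HMGA2 (2-sided exact permutation p = 0.1). An exact permutation test of 3 against 3 libraries cannot go below a 2-sided p of 0.1. All exact permutation tests here treated the libraries as exchangeable and left out the pairing by donor. All libraries came from 3 donors, and vector batch, virus dose and selection went with the vector, so the comparison measured the HMGA2 vector against the empty vector as used.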

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

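All tests of explanations in this part were chosen after the results they examine were seen.

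Counts on the strand opposite to the library kit, which no comparison used, held a signal at HMGA2 above the level in the control libraries. The HMGA2 libraries together had 1831 such counts assigned to HMGA2 (1071, 219 and 541) and the empty vector libraries 3. These were 2.35% of the HMGA2 counts of both strands, against 0.298% at the same gene in the empty vector libraries and 5.24 to 5.94% over all genes of a library. The antisense gene HMGA2-AS1, which overlaps HMGA2, had 1 count with the empty vector and 3 with HMGA2 on its own strand. Read pairs in no annotated gene were the other signal outside the gene counts, with a mean of 3.76% in the HMGA2 libraries against 2.70% with the empty vector. The source of neither was tested.

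Targets of p53 were higher with HMGA2, with a median log2 fold change of 0.81 over 22 genes. The list's call was borderline with an estimated correlation (camera adjusted p = 0.0471) and was lost there with the donor block (adjusted p = 0.463). GC content or gene length bias as the whole reason was argued against by a median of 0.71 with the correction (camera adjusted p = 6.39e-15 with the preset correlation). Scaling by library size moves all genes alike, and was argued against by a list median that stood 0.82 above the all-gene median, a distance that no choice of scaling changes. Higher p53 activity in the HMGA2 libraries required further targets to lean up. A second list of known targets was written after the gene results were seen and held genes already seen to be called. Only its 48 genes that did not pass in the group fit were therefore used. With the donor block 24 genes of the whole list were higher and 1 lower, against 14 and 0 in the group fit. The 48 thus still held genes called in the donor-block fit, and their lean is not independent of those calls. The 48 genes had a median of 0.48, with 40 above 0 and the highest of 10000 random lists at 0.29. Random lists leave out correlation between genes, and with it estimated the whole second list lost its call under the donor block (camera adjusted p = 0.0694, against 0.00471 without the block). A difference in virus dose or selection between the constructs cannot be told apart from an effect of HMGA2, since each construct was one arm in every donor (lowest donor median 0.84). The labels' protocols give 1 polybrene dose, transduction time and puromycin dose, and they give no virus dose.

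Some keratin, cornified envelope and kallikrein genes were higher with HMGA2. The 10 weighed here (KRT17, KRT14, KRT9, KRT80, KRT7, IVL, LCE1E, LCE2C, KLK5 and KLK6) were picked because they were called higher. Of all 19 keratin genes tested, 5 were higher and 0 lower by edgeR (12 and 0 with the donor block), while KRT5, KRT6A and KRT6B stayed too low to be tested. Epithelial cells in the HMGA2 cultures as the source were argued against by genes that epithelia express strongly: 14 of them, among them EPCAM, CDH1, KRT5 and KRT6A, summed to 4.46 CPM (2.22 to 7.06 per library) against 2.88 CPM with the empty vector, while IVL, KRT17 and KRT7 together gained 516 CPM. EPCAM was at 0.308 and 0.212 CPM and CDH1 at 0.767 and 0.768 CPM with the empty vector and HMGA2. KRT8, KRT18 and KRT19, which simple epithelia also express, were not among the 14 and were higher with the donor block, and 8 of the 9 tested members of the fixed epithelial list were above 0 (median 1.01). With the GC and length correction the median over the 10 genes was 5.46, against 5.53 without it. The correction moved the all-gene median only from −0.01 to −0.08, and the 10 genes were picked as called higher. The comparison could hardly have come out otherwise, so it decides nothing about GC content or gene length bias. Other explanations were not tested.

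Genes called higher lay next to each other more often than permuted labels did. Adjacent here means next in order among the tested genes of a chromosome, at any distance, with untested genes passed over. Some gaps were therefore wide, such as 120 kb between LCE1E and IVL and 971 kb between ACTBL2 and PLK2. Of 260 such genes, 30 adjacent pairs formed, against a mean of 4.69 and a highest value of 17 in 10000 permutations over 14338 placed genes. The 112 lower genes formed 3 pairs (mean 0.875, with as many in 578 of the permutations). With the donor block both directions formed more pairs than the permuted mean, with 123 for higher genes (mean 31.6, highest 54) and 29 for lower genes (mean 14.45, as many in 2 permutations). Reads shared between paralogs, overlapping genes or read-through as the whole reason were argued against by 12 pairs left without family members, overlaps and gaps under 10 kb (permuted mean 2.51, highest 10), such as LCE1E with IVL, NPAS3 with EGLN3 and FABP3 with SERINC2. GC content and expression level shared by neighbours were argued against by a highest value of 15 in permutations within bins of both. A regional effect of HMGA2 on chromatin is a possible explanation that was not tested.

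The splits of the 6 libraries are too few for a share under 0.05. For genes changed by the group fit, 1 of 10 splits reached the real value of 372, and the highest other was 0. With the donor block, 1 of the 4 splits that part all donors reached 1129, and the highest other was 0. For gene lists, 5 of 10 splits had at least the real 9, and the highest other had 16. The 4 splits with more lists than the real split all placed both donor 1 libraries on the same side. Each of them also kept both libraries of another donor together on the other side, and the reason was not tested. Among the splits that part all donors the highest other was 8.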

How the results depend on the processing

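The correction for GC content and length, and the donor block combined with that correction, with the fold minimum, with an estimated correlation and with fry, were added after the data were seen. The group fit gave 372 genes changed (260 higher, 112 lower) and 9 lists. Alternatives that kept all counts within 1.5 times were size factors of the DESeq2 kind (369 genes), library totals (462), removal of HMGA2 (369), the CPM filter (362), unstranded counts (386), limma-voom (308) and no robust estimation (374). Counts of genes changed, higher and lower moved to 1129, 673 and 456 with the donor block, 1122, 670 and 452 with unstranded counts and the block, 884, 543 and 341 without a filter, 1200, 700 and 500 with DESeq2, 1608, 919 and 689 with DESeq2 and the block, 1247, 728 and 519 with limma-voom and the block, and 1418, 666 and 752 with the GC and length correction and the block. That correction alone moved the lower genes to 180. A tested minimum fold of 1.5 left 138, 107 and 31, by its construction. Leaving out donors or single libraries gave 0 to 1156 changed, 0 to 652 higher and 0 to 504 lower. With the block, these counts were 132, 92 and 40 without donor 1 and 859, 521 and 338 without donor 3. Single libraries were left out without the block. The counts fell to 21, 17 and 4 without the HMGA2 library of donor 2. They were 85, 71 and 14 without that of donor 1 and 119, 93 and 26 without that of donor 3. Without the empty vector library of donor 1 they were 238, 167 and 71. For the empty vector libraries of donors 2 and 3 they were 129, 73 and 56, and 202, 134 and 68. The leave-outs gave HMGA2 log2 fold changes of 5.70 to 6.60. By edgeR without the block, HMGA2 was not past the threshold without donor 1 (5.96, adjusted p = 0.0538) or donor 2 (6.49, adjusted p = 0.0799). It passed without donor 3 (5.76, edgeR adjusted p = 0.00227), where as many libraries were left. With the block it also passed without donor 2 (6.60, edgeR adjusted p = 5.97e-07). Lists past the threshold numbered 16 without a filter, 1 with an estimated correlation, 1 by fry, 0 with an estimated correlation and the block and 2 by fry with the block, and 6 to 13 in the leave-outs. The cell cycle list reversed to a mean of 0.18 without donor 2, 0.21 without donor 2 under the block and 0.055 without the empty vector library of donor 2, while without donor 3 it was −1.10. Except where construction is named, the cause was not tested. No gene called by the group fit changed sign in any setting. This says little, since all 372 already had the same direction in all 3 donors. Over all settings the named genes kept their direction and their side of the threshold, called or not, 2098 times, gained a call 352 times and lost it 337 times. For lists these were 757, 58 and 47 times, with the 3 reversals above, and 77 values of lists and 14 of genes moved without a call. The donor block gained 44 named genes and 4 lists and lost 1 list, pericyte markers, and changed no other call. Every alternative listed was run. On data simulated at this depth from each fit's own model, the group fit recovered 8% of 2-fold changes and the donor-block fit 48%. The 2 fits were not run on the same simulated data. In its own simulation the group fit missed most 2-fold changes.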

Other observations

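The added gene lists and the detection counts in this part were chosen after the data were seen.

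Some genes of striated and cardiac muscle rose in these myometrial cells. ANKRD1, a stretch-responsive titin partner, rose by 4.74 (SE 0.79, edgeR adjusted p = 0.0348), the atrial myosin light chain gene MYL7 by 4.32 (SE 0.67), the pacemaker channel gene HCN4 by 4.74 (SE 0.96), TRIM55 by 4.08 (SE 0.59) and the small GTPase gene RRAD by 4.25 (SE 0.54). MYOD1, the master regulator of skeletal muscle, had 0 counts with the empty vector and 143 with HMGA2, at least 40.5-fold higher. Of 49 such genes in a list written after some of them were seen to be called, 22 had enough counts to be tested. Of these, 10 were higher and 0 lower in the group fit. MYOD1, with no count in the empty vector libraries, could pass the count filter only through the HMGA2 libraries, which favours rises among the tested genes. Some members leaned lower without a call, such as MYH3 at −2.13 (SE 0.86). A list test on genes chosen in that way decides nothing, so none is given.

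Genes of retinoic acid handling moved in both directions and did not pass as a list. The receptor gene RARB changed by −2.68 (SE 0.48, edgeR adjusted p = 0.0354), the retinal reductase gene DHRS3 by −2.95 (SE 0.57), the retinol dehydrogenase gene RDH10 by −1.33 (SE 0.25) and the nuclear receptor gene NR2F1 by −1.81 (SE 0.33). TGM2 rose, and CYP26B1, which breaks retinoic acid down, was at 3.84 (SE 1.10) and passed with the donor block (edgeR adjusted p = 0.00447). That list of 25 had 1 higher and 4 lower (2 and 8 with the donor block), a median of −0.45 and a camera adjusted p of 0.0590 (adjusted p = 0.155 with an estimated correlation). Imprinted genes (27 tested) had 2 higher, MEST and INPP5F (1.35, SE 0.18), and 0 lower (4 and 1 with the donor block). The imprinted list had a median of −0.18, a mean of 0.04 and a camera adjusted p of 0.451 on the higher side. Among the further p53 targets the phosphatase gene PPM1D rose by 1.74 (SE 0.18, edgeR adjusted p = 0.00721) and CSF1 by 2.18 (SE 0.37).

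Some genes called higher had no counts at all with the empty vector. Among the 260, 15 had 0 counts in all 3 empty vector libraries. The p53-induced noncoding RNA PINCR had 488 counts with HMGA2 (at least 138-fold higher), the cornified envelope gene LCE2C 485 (at least 137-fold) and the kallikrein gene KLK6 204 (at least 57.8-fold). ZSCAN4, an early embryonic transcription factor, had 116 counts (at least 32.9-fold higher) and the iron-binding lipocalin gene LCN2 95 (at least 26.9-fold). With libraries thinned to 9899481 counts, 19472 ± 777 genes had a count with the empty vector and 20806 ± 879 with HMGA2, higher in 3 of 3 donors (2-sided exact permutation p = 0.2).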
